A study of Lepeophtheirus salmonis with 12 samples.

How the data were processed

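The study exposed copepodids, the free-swimming infective larvae of the salmon louse Lepeophtheirus salmonis, to 1 µg/L of the pyrethroid cypermethrin or to plain seawater for 24 h. Per the labels, each of the 12 beakers held about 500 larvae in 500 mL, each beaker gave 1 pool and 1 RNA extraction, and each group had 6 pools. Each pool was labelled with Cy5 and hybridised beside a Cy3 reference pool made from all conditions. The sample was in Cy5 on every array, so a higher log ratio means more transcript in the pool, and a constant dye effect cancels between groups. There was no dye swap.

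Spot intensity on a linear scale was measured by the authors with ImaGene 8.0.1, per the file headers, as the mean signal of each spot with the mean and SD of its local background. Per the file headers, the other columns used, the flag code and the saturation mark, were also deposited by the authors from ImaGene. The authors also deposited a matrix of log2 sample over reference ratios, lowess-normalized per the file headers. The series value table held the same log2 numbers as the deposited lowess matrix, with a largest difference of 0, so both alternatives made from them are identical. Column medians of that matrix lay between -0.01 and 0.02. The names of the genes are the homology descriptions deposited with the array: 16826 of the 38132 probes had a description and 21306 had none. Such a description is a best match in another species, and different probes with the same description can measure different louse genes. The table of louse locus tags and symbols held no identifier shared with the array and was not used here.

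Analysis started from the scanner intensities with limma 3.58.1 in R 4.3.3. Background was corrected with normexp and an offset of 50, and log2 ratios were normalized within each array by loess with control spots at weight 0. A probe was tested when its Cy5 signal exceeded the local background by 2 SD on at least 6 of the 12 arrays, which left 20911 probes, 12799 of them described. Groups were compared with lmFit and eBayes with an intensity trend, two-sided, with Benjamini-Hochberg adjustment and a threshold of 0.05. Fold changes are cypermethrin over control on the log2 scale. For a probe above background on no array of a group, a fold was computed in Cy5 after loess and Aquantile. Values of that group below a floor, the dimmest signal above background on each array, were raised to it. Without balanced swaps this fold is open to a dye bias that varies between arrays, since only a constant one cancels.

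The 25 gene lists, the tests, the alternatives and the rule for named genes were fixed before the data were examined. Lists matched words in the descriptions, so some members share only a word with the list's name, and used the brightest probe of each description. Lists of at least 5 genes were tested with camera at a preset correlation of 0.01, beside camera with an estimated correlation and fry. The named genes are the 12 largest rises and 12 largest falls among described probes past the threshold, up to 4 genes of smallest p in each list, and the sodium channel and detoxification genes whether or not they passed. Probes without a description are named only for the largest rise and fall.

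The fit was tested on simulated data with the residual SDs of the 20911 probes and 200 changed probes. For cypermethrin against control it recovered 37.3% of the changes of 1.5-fold, 89.6% of those of 2-fold and 98.5% of those of 4-fold, with 11 false calls. In simulated data the list test called a list of 31 genes raised by 0.3 and 0 of 21 others. The simulated noise was independent between probes, unlike that of real arrays. It also had the same SD in both groups, whereas in the data the median ratio of control to cypermethrin SD was 1.46.

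Median Cy5 signal per array ran from 264.6 to 418.9 over a local background of 120.8 to 169.2, and between 48.6% and 62.6% of probes exceeded background. The number of arrays limits the precision. The 12 arrays lay on 8 slides scanned on 4 days, per the file headers. Both groups shared 3 slides and 2 scan days; 4 slides and 2 scan days held 1 array each, and 1 slide held 2 controls. Alternatives covered background correction, normalization, the filter, flagged spots, Cy5 alone, blocks for replicate number, slide, slide series and array position, array weights, the variance trend, and each array left out. Scan day, array brightness, a cuticle score and the removal of control 6 with cypermethrin 4 were added after seeing the data.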

Results

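Gene expression was measured on two-colour arrays in 12 pools of copepodids of the salmon louse, an ectoparasitic crustacean of salmon, after 24 h in seawater (6 pools) or in 1 µg/L cypermethrin (6 pools). Cypermethrin is a pyrethroid, a class of insecticide that holds voltage-gated sodium channels of nerves open. The comparison asks which transcripts differ between exposed and unexposed larvae. Arrays correlated at 0.67 to 0.95 over the tested probes. Cypermethrin pools resembled each other more closely (median r 0.91) than control pools did (median r 0.81).

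Zinc metalloproteinases nas-7 and nas-4, chymotrypsin A chain C, putative ascorbate peroxidase and heat shock protein beta-1 were among the transcripts that rose in exposed larvae. Putative carbonic anhydrase 5, 72 kDa type IV collagenase, both subunits of the SUMO-activating enzyme and 3 proteasome subunits were among those that fell. The calls of chymotrypsin A chain C, heat shock protein beta-1, the SUMO-activating enzyme and the proteasome subunits were lost in most fits with 1 array left out. In limma's test, 459 of 20911 probes changed, 285 upward and 174 downward, and 299 changed by at least 1.5-fold (203 upward, 96 downward). The risen probes carried 100 descriptions and the fallen probes 102. The changes were modest, with a median size of 0.64 on the log2 scale, and 81.9% of the changed probes had an adjusted p between 0.03 and 0.05. The groups did not overlap at 460 probes, 266 of them changed, where chance gives 0.216% of probes. With median centring in place of loess, which shifted the median of all probes to 0.16, 361 probes rose and 9 fell, and with the authors' lowess values 270 rose and 257 fell, so the balance of rises and falls depended on the normalization.

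The number of changed probes rested on single arrays and on the model of the arrays. It was 56, 60 and 87 without control 3, 4 or 5, 49, 50, 46, 48 and 45 without cypermethrin 1, 2, 3, 5 or 6, and 1669 and 1019 without control 1 or 2. It was 14 with scan day as a block, 34 with array position as a block, 75 with slide series as a block, 26 with Cy5 brightness as a covariate, and 0 with slide as a fixed block, where limma still gave 3843 probes at an unadjusted p under 0.05. With slide as a random block it was 337, all of them among the 459, with an estimated correlation within slides of -0.02. At an unadjusted p under 0.05 limma gave 4399 probes in the main fit and 2542 with brightness as a covariate. With 1 array left out such probes numbered from 3248 (without control 4) to 5508 (without control 1). On the 3 slides that held a pool of each group, 455, 451 and 459 of the 459 probes moved the same way as in all arrays, and on both shared scan days all 459 did. These pools also took part in choosing the probes; over all tested probes the shares were 74.9%, 68.7% and 80.1% for the slides and 80.9% and 76.5% for the scan days.

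The largest rise was of a probe described as Activation peptide, with a log2 fold change of 2.49 ± 0.31 (SE, n = 6 and 6, limma adjusted p = 0.00248). Its log ratio to the reference was 0.22 ± 0.76 (SD) in control and 2.71 ± 0.43 (SD) in cypermethrin pools, and the other probe of this description stood at -0.52. Zinc metalloproteinase nas-7, an astacin-type protease, rose by 2.38 ± 0.41 (SE, adjusted p = 0.0183), and both of its probes rose. Tissue-type plasminogen activator chain B, a serine protease, was not well above background on any control array, and its log ratio rose by 1.67 (limma adjusted p = 0.0137). In Cy5 its mean was 8.62 in cypermethrin pools and 7.15 in control pools on the log2 scale, 2.79-fold higher. The floor left that control mean unchanged, so this fold is the measured difference and not a bound. Putative ascorbate peroxidase rose by 1.33 with the smallest adjusted p of all probes, 9.66e-05, and 82 kDa matrix metalloproteinase-9 rose by 1.40, although another probe of that description stood at -0.97. Of 6 putative ascorbate peroxidase probes 2 rose and the lowest stood at -0.02. The named one was above background on 3 control and 6 cypermethrin arrays. The remaining 7 of the 12 largest rises, with log2 fold changes unless a fold is named, were membrane metallo-endopeptidase-like 1 (1.55), a probable serine protease (1.47), chymotrypsin A chain C (1.19), zinc metalloproteinases nas-15 (2.15-fold) and nas-4 (1.09), heat shock protein beta-1 (1.08) and protein JTB (1.06). Of 18 nas-15 probes 2 rose and the lowest stood at -0.07. Of 7 heat shock protein beta-1 probes 2 rose and the lowest stood at -0.22.

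Putative carbonic anhydrase 5, an enzyme of carbon dioxide and bicarbonate exchange, fell by 1.20 ± 0.17 (SE, adjusted p = 0.00474), and both of its probes fell. A probe of 72 kDa type IV collagenase fell by 1.15 (adjusted p = 0.00672). Of the 11 probes of this description 4 fell and 0 rose past the threshold, and the highest stood at 0.99. Both subunits of the SUMO-activating enzyme, which starts the attachment of the small protein SUMO to other proteins, fell, with a fold of 2.15 for subunit 1 and 1.88 for subunit 2. Subunit 1 (limma adjusted p = 0.0489) kept its call in 3 of the 12 fits with 1 array left out. Subunit 2 (limma adjusted p = 0.0318) kept it in 4. Coatomer subunit beta, of vesicle coats, fell by 1.12, MOSC domain-containing protein 2 by 1.08 and COP9 signalosome complex subunit 4 by 0.92. Replication protein A 32 kDa subunit, which binds single-stranded DNA, fell by 0.83 with 4 of its 6 probes past the threshold, and methyltransferase-like protein 11A fell by 0.88. Inosine-uridine preferring nucleoside hydrolase, spermine synthase and cystathionine beta-synthase each fell by 0.83. Of 3 spermine synthase probes 1 fell and the highest stood at 0.59. Of 8 cystathionine beta-synthase probes 2 fell and the highest stood at 0.28. Of 8 coatomer subunit beta probes 1 fell and the highest stood at 0.15. Of these 24 largest changes, all kept their direction when any array was left out, 8 kept their call each time, and 4 kept it with Cy5 brightness as a covariate. Over the 45 changed probes that the rule for named genes gave, in the lists too, 12 kept their call whichever array was left out and 7 kept it with brightness. Outside the 24 largest, those 12 comprised the brighter probes of zinc metalloproteinases nas-7 and nas-4, 40S ribosomal protein S13 and C092R089. The other list genes that changed by their brightest probe kept their call in 2 to 5 of the 12 fits; dimmer probes of list genes were named after their values were seen and were not followed through these fits. Among probes with no description, C092R089 rose by 1.97 (adjusted p = 0.00281) and C040R141 fell by 1.24 (adjusted p = 0.0409).

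**Figure D1:**
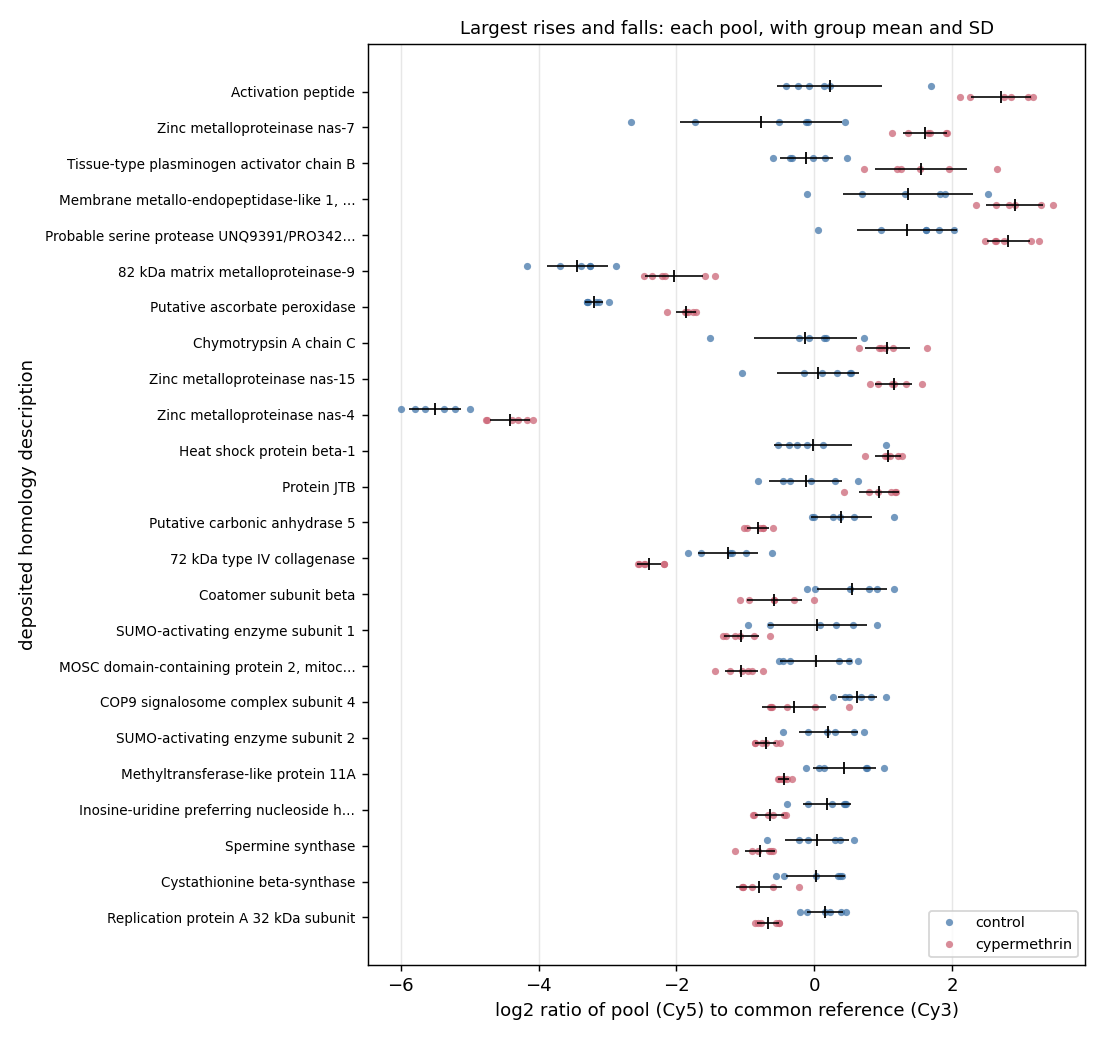
Log2 ratio of each pool to the common reference for the 12 largest rises and 12 largest falls, with 6 control and 6 cypermethrin pools per gene as points and the group mean with its SD as a bar. Control pools are more spread than cypermethrin pools for most of these genes, for example with an SD of 1.18 against 0.31 for zinc metalloproteinase nas-7.

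Of the 22 lists tested, digestive proteases alone passed camera's threshold, upward (31 genes, median log2 fold change 0.16, camera adjusted p = 0.0121). The list's call was lost with an estimated correlation (adjusted p = 0.107 with an estimated correlation), with slide as a fixed block (adjusted p = 0.135) and in the Cy5 channel alone (adjusted p = 0.156). 4 of its genes rose, 0 fell, and 7 rose when adjusted over the list alone. The risen genes were zinc metalloproteinases nas-7 (2.15 for its brighter probe) and nas-4 (1.03), chymotrypsin A chain C (1.11) and neurotrypsin (0.56), a serine protease named for nerve tissue in vertebrates. The list's words also matched protease inhibitors, among them antichymotrypsin-2 and leukocyte elastase inhibitor, and carboxypeptidases of other functions, such as lysosomal Pro-X carboxypeptidase. The median was 0.11, 0.20 and 0.25 within the 3 shared slides and 0.24 and 0.14 within both shared scan days. On the slides 18, 20 and 21 of the 31 genes were positive, and on the scan days 23 and 18, against 25 in all arrays. These pools also took part in the list's call. Of 100 groupings of the same arrays, the real one included, this list passed in 12. The other passing groupings all kept most pools of each group together and so held part of the exposure contrast. The 12 is therefore not a rate by chance alone. In other groupings a shift of at least 1 list was common, as given among the flagged results.

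Among 50 heat shock proteins and chaperonins, 3 rose, 0 fell, and 3 rose adjusted over the list alone, while the list as a whole did not pass (median 0.02, adjusted p = 0.75). Heat shock protein beta-1 and alpha-crystallin B chain (0.63, adjusted p = 0.0349) are small heat shock proteins, which hold unfolding proteins in solution. The third, T-complex protein 11-like protein 1 (0.55), matched the list by its name and is not a chaperonin, and Tcp11 (0.62, adjusted p = 0.0847) matched in the same way. Of 14 endoplasmic reticulum stress proteins, 1 rose, probable protein disulfide-isomerase A6 (0.47, adjusted p = 0.048), 2 rose adjusted over the list alone, and the list's adjusted p was 0.18. Protein disulfide-isomerase stood at 0.57, endoplasmin at 0.43 and hypoxia up-regulated protein 1 at 0.37, none past the threshold. Heat shock protein beta-1 and alpha-crystallin B chain each kept their call in 4, and the other risen genes of both lists in 2, of the 12 fits with 1 array left out.

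Of 35 antioxidant and metal-binding proteins, 2 fell and 0 rose, with 7 fallen adjusted over the list alone (list median -0.06, adjusted p = 0.0647). The 2 were the copper chaperone for superoxide dismutase, which delivers copper to that enzyme (-0.63, adjusted p = 0.0463), and glutaredoxin 3 (-0.61, adjusted p = 0.0474). The list passed, downward, in 4 of 37 alternatives (adjusted p from 0.0281 to 0.733 over all 37), among them the fit without control 2 (0.0328) and median centring (0.0281), where its median of 0.08 lay below the 0.16 of all probes. Monothiol glutaredoxin-S11 (-0.53) and thioredoxin-related transmembrane protein 1 (-0.42) did not pass. Of 115 ubiquitin and proteasome genes 3 fell, all subunits of the proteasome core, namely beta type-3 (-0.57), beta type-6 (-0.51) and alpha type-2 (-0.46). Adjusted over the list alone, 12 fell and 5 rose, and the list did not pass (median -0.08, adjusted p = 0.141), except with all probes of a gene (adjusted p = 0.0179, in a range from 0.0179 to 0.733). Each of the 3 proteasome subunits, the copper chaperone and glutaredoxin 3 kept its call in 4 of the 12 fits with 1 array left out. Proteasome assembly chaperone 2 stood at -0.53 (adjusted p = 0.0516).

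None of the genes in the cytochrome P450, conjugation and esterase lists passed limma's threshold; at an unadjusted p under 0.05 there were 2 of 10 genes of the cytochrome P450 list, 3 of 23 genes of the conjugation list and 0 of 3 esterases. All but 1 of the 10 genes of the cytochrome P450 list had a positive log2 fold change (median 0.18, list adjusted p = 0.172) and 0 passed adjusted over the list alone. The list passed, upward, in 2 of 37 alternatives, Cy5 alone (adjusted p = 0.048) and slide as a fixed block (0.0352), in a range from 0.0352 to 0.788. Cytochrome P450 2L1 stood at 0.42 (adjusted p = 0.149), a gene described only as cytochrome P450 at 0.53, cytochrome P450 9f2 at 0.25 and 315a1, named after an insect enzyme of ecdysteroid synthesis, at -0.27. NADPH--cytochrome P450 reductase (0.18), which passes electrons to these enzymes, matched the list by its name and is not a cytochrome P450. Of the 23 genes of the conjugation list 0 passed and 2 fell adjusted over the list alone (median -0.06, adjusted p = 0.41). The list's words also matched enzymes that do not conjugate foreign compounds, among them the sulfotransferases of heparan sulfate, of other carbohydrates and of protein tyrosine, and UDP-glucuronic acid decarboxylase 1. Sulfotransferase 1C4 was lowest at -0.56 (adjusted p = 0.0628), and UDP-glucuronosyltransferase 2A3 stood at -0.44, glutathione S-transferase DHAR1 at -0.40 and glutathione S-transferase Mu 3 at -0.22. Sulfotransferase 1C4 passed, downward, in 7 of 34 alternatives (limma adjusted p from 0.0237 to 0.277 over all 34). DHAR1 passed, downward, in 1 of 34 (from 0.0434 to 0.449). The 3 carboxyl- and cholinesterases, too few to test as a list, stood at 0.04 (esterase FE4), -0.04 (carboxylesterase, by its domain name) and 0.004 (carboxylesterase 8), with signs that turned under other settings. The only probe naming a sodium channel that passed the intensity filter was of sodium channel protein Nach, which belongs to the amiloride-sensitive family and not to the voltage-gated channels (0.09, adjusted p = 0.862, above background on 2 control and 4 cypermethrin arrays). The list of 5 sodium channels and sodium-potassium pumps had a median of -0.06 (adjusted p = 0.75), with sodium/potassium-transporting ATPase subunit alpha-1 at -0.36 and 1 gene at an unadjusted p under 0.05. Of the 10 genes that matched the ABC transporter list by name, 1 fell, and 1 fell adjusted over the list alone. It was ATP-binding cassette sub-family E member 1 (-0.49, limma adjusted p = 0.0474), a factor in ribosome recycling and not a membrane pump. Sub-family B members 7 (0.37) and 8 (-0.28) and ABC transporter G family member 20 (0.42) did not pass.

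In metabolism, 3 of 34 genes of glycolysis and gluconeogenesis fell: glucose-6-phosphatase 2 (-0.82, adjusted p = 0.0329), mitochondrial enolase superfamily member 1 (-0.74), which is not the glycolytic enolase, and hexokinase-2 (-0.55). The list's median was 0.01 and its mean -0.06, so their signs differed, and its adjusted p was 0.75; adjusted over the list alone 3 fell and 1 rose. Of 60 lipid genes 1 rose, very long-chain-fatty-acid--CoA ligase bubblegum (0.80, adjusted p = 0.0425), with a list adjusted p of 0.761, and 1 rose adjusted over the list alone; a dimmer probe of delta(5) fatty acid desaturase B fell (-0.58, adjusted p = 0.0416). In the citric acid cycle (31 genes, median -0.06, adjusted p = 0.75), oxidative phosphorylation (65 genes, median -0.03, adjusted p = 0.41) and amino acid metabolism (27 genes, median 0.08, adjusted p = 0.429) 0 genes passed limma's threshold, with the smallest p of the 3 lists in ATP synthase mitochondrial F1 complex assembly factor 2 (-0.58, limma unadjusted p = 0.00146). At an unadjusted p under 0.05 there were 4, 6 and 6 genes in these lists; adjusted over the list alone 0 passed in the citric acid cycle and oxidative phosphorylation, and 2 rose and 3 fell in amino acid metabolism. These counts take the brightest probe of each gene. Tyrosine aminotransferase stood at 0.72 (adjusted p = 0.0831) by that probe, and its other probe rose (0.76, adjusted p = 0.0458), as did another probe of proline dehydrogenase (0.73, adjusted p = 0.0425), while another probe of cytochrome c oxidase assembly protein COX15 homolog fell (-0.39, adjusted p = 0.0472). Of 73 cytosolic ribosomal proteins 1 rose, 40S ribosomal protein S13 (0.80, adjusted p = 0.0107), in a list with a median of 0.01 (adjusted p = 0.842), and 1 rose adjusted over the list alone.

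Among the lists that mark tissues of the whole larva, digestive proteases passed, and the others did not. As given above, that call was lost with an estimated correlation (camera adjusted p = 0.107), and the list also holds genes that are not digestive proteases. Of 37 genes of the muscle list 29 had a positive log2 fold change (median 0.10, adjusted p = 0.0647), including titin, of the sarcomere, at 0.47. Myosin-Va (0.59), myosin-XV (0.41) and myosin-VIIa (0.35), among other members, matched the list by name and are unconventional myosins that are not specific to muscle. Another of the 4 myosin-Va probes (0.62, adjusted p = 0.038) and 1 of the 45 titin probes (0.66) rose. The muscle list passed, upward, in 7 of 37 alternatives (adjusted p from 7.5e-06 to 0.788 over all 37), among them the fits without control 1 (adjusted p = 0.0381), control 6 (0.0133) or cypermethrin 1 (0.03). Neuronal receptors and synapse proteins (31 genes, median -0.03, camera adjusted p = 0.963) had a negative median and mean (-0.04), while camera's direction was upward. Cuticle and chitin proteins (11 genes, median -0.02, camera adjusted p = 0.951) had a negative median, a downward direction in camera and a mean that rounded to 0. Immune and haemocyte proteins (11 genes, adjusted p = 0.75) included protein toll at 0.63 (adjusted p = 0.0671), of whose 6 probes 2 others rose (0.77 and 0.86). Lysosomal hydrolases (20 genes, median 0.05) had an adjusted p of 0.753, and cell cycle and DNA replication genes (50 genes, median -0.09) one of 0.41, although a dimmer probe of mitotic spindle assembly checkpoint protein MAD2A fell (-0.78, adjusted p = 0.048). Of 16 apoptosis genes 1 rose, apoptosis 2 inhibitor (0.56, adjusted p = 0.0459), in a list with an adjusted p of 0.761, where 1 rose and 1 fell adjusted over the list alone. In the other lists of this paragraph 0 genes passed limma's threshold over all genes by their brightest probe. At an unadjusted p under 0.05 there were 6 muscle, 2 neuronal, 1 cuticle, 1 immune, 3 lysosomal and 16 cell cycle genes, and adjusted over the list alone 1 immune and 1 lysosomal gene rose. The 2 vitellogenins, yolk proteins, stood at -0.20 and -0.17 and the 2 moulting factors, Protein SGT1 homolog ecdysoneless and Broad-complex core protein isoform 6, at 0.13 each by the brightest probe, none past the threshold and both lists too small to test. Of the 13 Broad-complex core protein isoform 6 probes, 1 other rose (0.89, adjusted p = 0.0318).

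**Figure D2:**
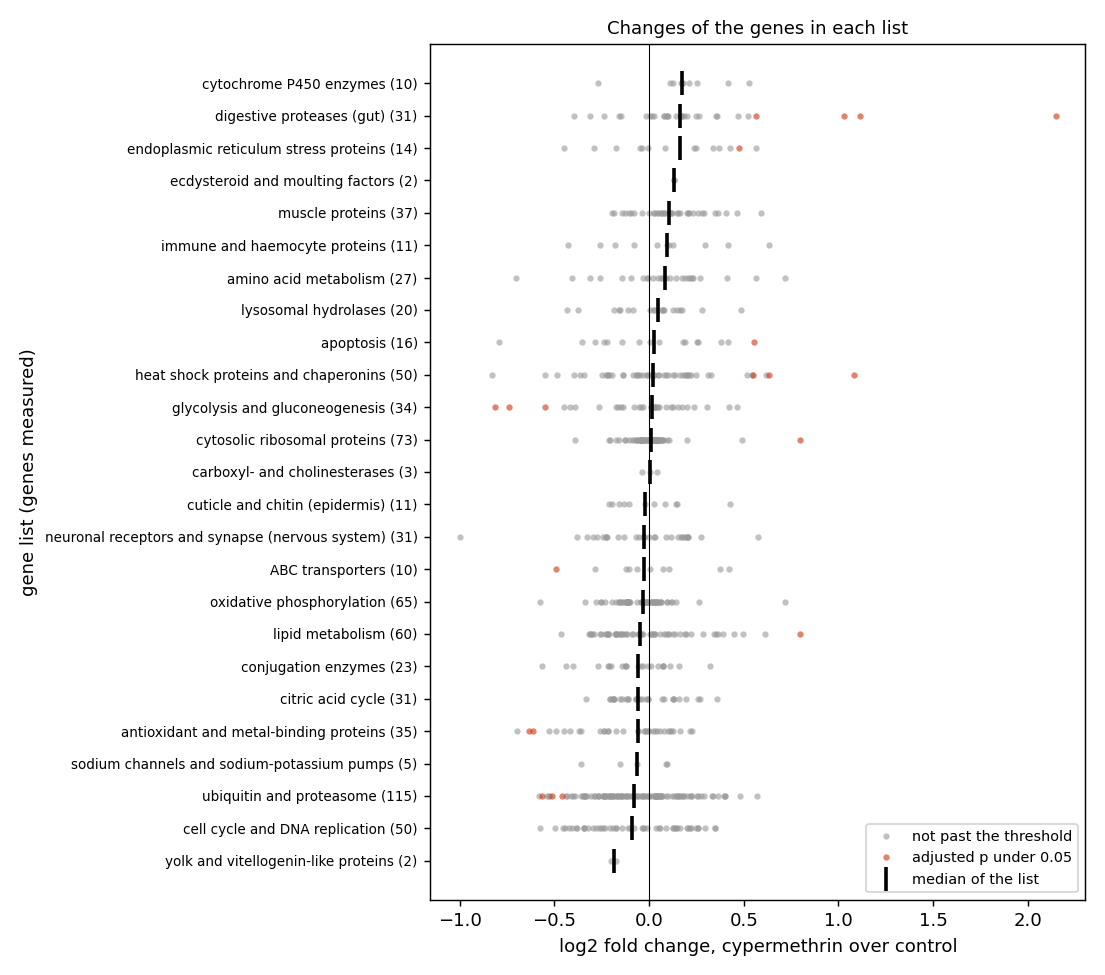
Log2 fold change, cypermethrin over control, of each measured gene in the 25 lists, with genes past the threshold in red, other genes in grey and the list median as a bar. The 4 risen digestive proteases lie between 0.56 and 2.15, apart from most genes of their list.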

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

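The tests of brightness, of the cuticle score, of scan days and of chance for the spread of controls were chosen after the result was seen; the other tests below were set before. In 290 groups of 6 pools (each named gene and list mean in each group), 13 held a pool far from the other 5, where chance gives about 14.5, so the number of such pools is no more than chance gives. No list mean was among them.

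In control 6 vitellogenin-2 stood at 3.82, against -2.29 to -0.76 in the other controls, neuroligin-4 at 3 against -0.62 to 0.34, and ABC transporter G family member 20 at 0.86 against -1.28 to -0.63. In control 1 the Activation peptide probe stood at 1.70, against -0.41 to 0.23 in the other controls, towards the level of the exposed pools. In cypermethrin 4 the carboxylesterase named by its domain stood at 0.61 against 1.26 to 1.47, ATP-binding cassette sub-family B member 7 at 0.08 against 0.37 to 0.54, bubblegum at 0.41 against 1.01 to 1.33, and vitellogenin-5 at -0.17 against 0.64 to 0.78. In cypermethrin 6 putative ascorbate peroxidase stood at -2.13 against -1.87 to -1.72 and programmed cell death protein 2 at -0.31 against 0.03 to 0.11. In cypermethrin 5 lysosomal alpha-mannosidase stood at -1.83 against -1.41 to -1.21 and MAD2A at -1.25 against -0.94 to -0.76. In cypermethrin 1 Peptidase_C1A stood at 0.60 against 0.76 to 0.84.

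The first pattern is the number of changed probes. Among 100 of the 462 splits of the 12 arrays, 1, the real one, gave as many (459, highest other 458). For changes of at least 1.5-fold it was also 1 (299, highest other 277). Among the splits drawn, chance was thus an unlikely source of both, but narrowly. It was not excluded, since the other splits were not examined. All splits ignore slides and scan days, the split with 458 exchanges control 2 and cypermethrin 4, and 96 splits gave 0. With scan day as a block 14 probes changed, with slide as a fixed block 0 and as a random block 337, and these splits do not test a grouping within slides or days. A change of the Cy3 reference made up 0.076 of the change of the log ratio (median over the changed probes), which argues against the reference channel, while the fold with the cuticle score as a covariate, 0.992 of its size, excludes nothing, since a score so alike in both groups (-1.35 ± 0.36 and -1.40 ± 0.44 (SD), exact two-sided permutation p = 0.831, n = 6 and 6) can hardly move it. With Cy5 brightness as a covariate it kept 0.872, from a median size of 0.64 (SE 0.14) to 0.57 (SE 0.15), and 25 of 459 calls held; with a single quantity of that fit put into the other at a time, 74 of the 459 calls held with its folds, 203 with its standard errors and 333 with its degrees of freedom, so each alone ended calls. Brightness was 7.49 ± 0.31 (SD) in control and 7.73 ± 0.20 (SD) in cypermethrin arrays on the log2 scale (exact two-sided permutation p = 0.143, n = 6 and 6), so a share of the change from brightness cannot be told apart from the exposure.

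For the number of shifted lists, 67 of the 100 splits gave at least 1 list, the highest other 6, so chance could not be excluded. Digestive proteases passed in 12 of the splits, and in 7, the real one included, their adjusted p was as small. Each of the other splits in which they passed kept most pools of each group together. Both counts thus include part of the exposure contrast and cannot serve as a rate by chance for this list.

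The second pattern is that the mean log ratio of the 12 largest rises differed among pools within groups, from -1.61 in control 6 to -0.11 in control 1 and from 0.28 in cypermethrin 4 to 0.91 in cypermethrin 3, a mean in which widely spread members such as nas-7 (control SD 1.18) weigh more than putative ascorbate peroxidase (0.13). Its deviations from the group means correlated with those of Cy5 brightness (Pearson r = 0.674, permutation p = 0.0418, adjusted over 2 relations 0.0836; Spearman rho = 0.734, p = 0.0195, adjusted 0.039; r = 0.572 without the 2 arrays farthest from the median, n = 12), so brightness may contribute. The correlation with the cuticle score was r = -0.40 (permutation p = 0.188, adjusted 0.188; rho = -0.573, p = 0.0543, adjusted 0.0543; r = -0.282 without the 2 farthest arrays). Arrays on the same slide differed by 1.09 times the mean of all pairs. Such pairs came only from the 3 slides with both groups and the 1 slide with 2 controls. Among them control 6 (deviation -0.75) and cypermethrin 1 (0.19) lay farthest apart. With so few pairs the ratio cannot decide on shared slides. Cuticle expression, the 1 biological measure set against this pattern, stays open, and the labels give no other that differs between pools of a group.

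The third pattern is the larger spread among control pools, with a mean distance of 0.543 between arrays against 0.403 among cypermethrin arrays, a ratio of 1.35. Median correlations were 0.809 among controls, 0.859 without control 6 and 0.907 among cypermethrin arrays. When the arrays were regrouped, as large a ratio came up with p = 0.00216 (exact two-sided permutation test). Regrouped sets mix control and cypermethrin arrays, so their distances also hold the shift between the groups. The test therefore cannot decide whether the larger spread arose by chance. In the brightest 25% of probes the median ratio of SDs was 1.59, which argues against the noise of dim probes. The 4 controls scanned on the same day had a median correlation of 0.806 (0.809 without control 6, and at lowest 0.76 without another of them). That lay below the lowest among cypermethrin arrays, 0.841, which argues against differences between scan days. A noisier scan day was not tested and stays open, since that day held 4 controls but 2 cypermethrin arrays. A hypothesis that exposure made pools more alike, for example by a shared response, stays open, as does an uneven start of the control pools. Cy5 brightness was also more spread among control arrays (SD 0.31) than among cypermethrin arrays (SD 0.20). Its part in this pattern was not tested and stays open too.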

How the results depend on the processing

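Scan day, Cy5 brightness and the cuticle score as model terms, and the removal of control 6 with cypermethrin 4, were chosen after seeing the data; the other alternatives were planned. All 459 changed probes kept their direction in each alternative that tested them except the Cy5 channel alone (458 of 459), but the counts did not hold. The numbers of changed probes, and of those changed by at least 1.5-fold, were 136 and 122 with no filter on dim probes, where more probes were tested, 112 and 103 in the Cy5 channel alone, and 243 and 196 with no intensity trend. They were 0 and 0 with slide as a fixed block, where the estimate comes from 3 slides, 337 and 240 with slide as a random block, 75 and 68 with slide series as a block, 34 and 33 with array position as a block, 14 and 14 with scan day as a block, and 26 and 25 with Cy5 brightness as a covariate. Array weights gave 1478 and 696, and leaving out control 6 and cypermethrin 4 gave 663 and 474. Leaving out 1 array gave 45 to 1669 changed probes and 42 to 820 changed by at least 1.5-fold. Where samples or degrees of freedom were not reduced, the cause was not tested.

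The share of rises among the changed probes was 62.1% with loess, 97.6% with median centring and 51.2% with the authors' lowess values. Equal replicate numbers did not mark shared samples: the deviations of the 6 pairs correlated at -0.12, -0.06, 0.27, 0.43, 0.08 and -0.23. With the replicate block, 316 probes changed, 244 of them by at least 1.5-fold, and 1 gene list shifted.

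The number of shifted lists was 2 with median centring, no filter, a raw Cy5 signal of 500 or more, Cy5 alone, slide as a fixed block, or control 6 and cypermethrin 4 left out, 3 with all probes of a gene, and 0 with an estimated correlation. It was 1 to 2 with 1 array left out. The further lists were muscle proteins, upward, with no filter, Cy5 alone, all probes of a gene, control 6 and cypermethrin 4 left out, and without control 1, control 6 or cypermethrin 1; antioxidant proteins, downward, with median centring, the raw signal filter, slide and without control 2; cytochrome P450 enzymes, upward, with Cy5 alone and slide; and ubiquitin and proteasome, downward, with all probes of a gene. Digestive proteases were among the shifted lists except with Cy5 alone, slide as a fixed block and the estimated correlation. The cause was not tested.

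The sign turned in 80 fits of 19 genes and lists, none past the threshold in either fit. Carboxylesterase 8 turned to -0.005 with no background correction, -0.010 with subtraction, -0.055 with scaling, -0.046 with the authors' lowess and series values, -0.028 with Cy5 alone, -0.046 with array position and -0.001 with the cuticle score. The carboxylesterase named by its domain turned to 0.123 with median centring, 0.043 with the lowess and series values, 0.083 with slide, 0.006 with array position, 0.079 with scan day and 0.036 without control 6 and cypermethrin 4. Vitellogenin-5 turned to 0.030 with slide, 0.042 with array position and 0.165 with scan day. Vitellogenin-2 turned to 0.048 with array weights, 0.838 with brightness and 0.140 without control 6 and cypermethrin 4. With brightness, esterase FE4 turned to -0.031, Broad-complex core protein isoform 6 to -0.067 and sodium channel protein Nach to -0.014, the last also to -0.025 without control 6 and cypermethrin 4. With Cy5 alone CBM_14 turned to 0.006, cuticle protein 7 to 0.114 and Peptidase_C1A to -0.094.

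The tested direction of a list turned in the following fits, given with the list's median there. The cuticle list stood at -0.031 with subtraction, -0.020 with the lowess and series values, -0.049 with array position, 0.029 with brightness and 0.039 with the cuticle score. The neuronal list stood at 0.157 with median centring, 0.075 with slide, -0.021 with brightness, -0.010 with the cuticle score, -0.057 without control 6 and cypermethrin 4 and -0.026 with fry. Cytosolic ribosomal proteins stood at 0.050 with median centring, -0.032 with slide and 0.003 without control 6 and cypermethrin 4. ABC transporters stood at 0.144 with median centring and -0.002 without control 6 and cypermethrin 4. Apoptosis stood at -0.051 with the raw signal filter, immune proteins at -0.005 with Cy5 alone, the citric acid cycle at -0.034 with slide, and lysosomal hydrolases at -0.069 and sodium channels and pumps at 0 with all probes of a gene.

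With 1 array left out, the ranges of those that turned were -0.010 to 0.232 for Broad-complex, -0.098 to 0.099 for the carboxylesterase named by its domain, -0.031 to 0.072 for carboxylesterase 8, -0.069 to 0.148 for esterase FE4, -0.019 to 0.257 for Nach, -0.746 to 0.686 for vitellogenin-2 and -0.329 to 0.035 for vitellogenin-5. They were -0.087 to 0.029 for ABC transporters, -0.160 to 0.066 for the cuticle list, -0.010 to 0.026 for ribosomal proteins and -0.069 to 0.029 for the neuronal list. The cause was not tested for any of these. Between 48.6% and 62.6% of probes exceeded background. Probes above background on fewer than 6 of the 12 arrays were left out of the main fit and were tested with no filter on dim probes.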

Other observations

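The words of the deposited descriptions were searched for themes outside the lists, a search chosen after the result was seen. Among 4466 descriptions, with the brightest probe of each, 50 rose and 44 fell, and 216 words that occur in at least 10 of them were tested for rises and for falls with Fisher's exact test (432 tests). None passed the adjusted threshold. The word metalloproteinase came closest, with 3 of 10 genes risen and 0 fallen (one-sided Fisher's exact p = 0.00015, adjusted p = 0.0648), and for falls the smallest p was that of the unspecific word type (5 of 99 genes fallen, exact p = 0.00265, adjusted p = 0.393), ahead of proteasome (3 of 29 genes fallen, exact p = 0.00273, adjusted p = 0.393).

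The first principal component of the log ratios held 31.4% of the variance and spanned both groups, from -49.81 in control 6 and -41.42 in control 4 to 36.67 in control 2, 30.50 in cypermethrin 1 and 29.90 in cypermethrin 3. Cy5 brightness on the log2 scale was 7.17 in control 6, 7.31 in control 4 and 7.98 in control 2. It was 7.495 in cypermethrin 1 and 7.96 in cypermethrin 3, and its relation to this component was not tested.

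The 320 spike-in control spots, used in no comparison, had a mean log2 ratio above the array median of 0.77 ± 0.19 (SD) in control and 0.72 ± 0.53 (SD) in cypermethrin arrays (exact two-sided permutation p = 0.851, n = 6 and 6), with the highest value, 1.72, in cypermethrin 4.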
